A study of Mus musculus with 22 samples.

How the data were processed

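RNA-seq was analysed from 22 prefrontal cortex libraries, 1 per mouse, in 6 groups of 3 lines. The Tcf20+/- and Phf14+/- lines are C57BL/6 and have 3 mutant and 3 WT libraries each. The MeCP2 KO line is an N129/FVB hybrid and has 5 and 5. Per the labels, each line has 1 litter value shared by mutant and WT libraries, so litter is tied to line and strain and cannot be separated from them.

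Total RNA was purified on columns, 250 ng was selected for poly(A) RNA and primed at random, and libraries were amplified over 15 PCR cycles, per the labels' protocols. Reads were handled with fastp 0.20.0 and STAR 2.7.2c, per the submitters' processing notes. The counting program, its strand setting, the genome build and the annotation are not given in the sources used here. The deposited values are raw whole-number counts per gene with no normalization, as their values show. Each table held 55421 versioned Ensembl gene IDs, of which 55154 matched a symbol without the version and 267 did not. Coordinates and gene lengths came from GENCODE M21 (GRCm38) by gene ID. Because the strand setting is unknown, overlapping and antisense genes are uncertain, as are genes with near-identical copies (globins, ribosomal proteins, Fdps, and mt-Atp6 and mt-Co2, which have nuclear copies). Counts of PCR-amplified reads are not independent molecules, so the floor of 3 counts covers counting error only.

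Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested within each line against its own WT with the edgeR quasi-likelihood F test (robust dispersion, two-sided), with Benjamini-Hochberg adjustment over all tested genes and calls at an adjusted p under 0.05. TMM factors lay between 0.9766 and 1.011, and the common biological coefficient of variation was 7.85% in the Tcf20+/- line, 6.73% in the Phf14+/- line and 11.7% in the MeCP2 line. Levels are given as CPM with TMM scaling and SD over libraries, and list means as log2 CPM with a prior count of 2. Differences between lines were tested as interaction contrasts in 1 edgeR fit of all 22 libraries. Correlations across genes were tested by permuting genotype labels within both lines, which gives p no smaller than 0.000794 for pairs with MeCP2 KO and 0.01 for the other pair. No sex term was fitted, since every library showed Y-linked and almost no Xist counts. Replicate numbers did not pair mutant and WT libraries in any line, by the correlation of their residuals.

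Before the data were examined, 32 gene lists were fixed from general knowledge, 14 of them markers of cell types or neighbouring regions and 1 of sex-linked genes, and 31 were tested. They covered the TCF20 complex and NCoR co-repressor, genes linked to Mecp2, activity, synapses, ion channels, neuropeptides, glucocorticoid response, cholesterol, autism genes, axon guidance, protein folding, interferon, ribosome, respiration and mitochondrial genes. Lists were tested with limma's camera at its preset correlation of 0.01 and with an estimated correlation, with Benjamini-Hochberg adjustment over the 31 lists, and their means by exact permutation of labels. Members were also adjusted over the list alone. The exact p can be no smaller than 0.1 for 3 against 3 and 0.00794 for 5 against 5. One list member, Ahsp, had no gene in the files.

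The genes named were set by a rule fixed before the data were examined. It took the 3 targeted genes, then up to 10 rises and 10 falls per line among called protein-coding genes with a mean of at least 1 CPM and no overlap between groups, then up to 4 called members per list or the 2 with the smallest p. It added the 10 genes with the smallest p where fewer than 10 passed. List members named for passing over the list alone or for a high level, such as Adora2a, Drd2, Egr1, Fos, Dusp6 and Plp1, were chosen after their values were seen.

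Each step was tested on simulated counts drawn from the real means and library sizes with 200 genes of at least 1 CPM changed. With 18348, 18975 and 19867 genes for Tcf20+/-, Phf14+/- and MeCP2 KO, edgeR recovered 28, 44 and 28% of the genes changed 1.25-fold, 72, 86 and 72% at 1.5-fold, 100, 98 and 98% at 2-fold and 100% at 4-fold in each line. Of its 164, 181 and 159 calls, 14, 17 and 10 were on unchanged genes. In separate runs with no gene changed, over 18342, 18956 and 19874 genes, it called 0, 4 and 0. Of 100 genes changed 2-fold in MeCP2 KO alone, the interaction test called 84 against Tcf20+/- and 90 against Phf14+/- (20263 genes). A list shifted 1.2-fold was called in each line, and a shift of 0.2 in long genes was recovered as 0.2, 0.201 and 0.202. Genes were drawn independently, so the effect of correlation among list members on the list test was not simulated. The adjusted threshold depends on how many genes change, so the recovered shares hold for 200 changed genes and may be lower with fewer.

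Alternatives were DESeq2-style factors, no count filter, DESeq2, limma voom with sample weights, all 22 libraries in 1 fit, a block by replicate number, other thresholds and each replicate left out in turn. Alternatives chosen after seeing the main results were equal depth by random thinning (its predictions were written before its own values were seen), a striatal or olfactory marker covariate, and leaving out pairs of libraries that stood apart. Splits of the samples were limited to 100. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.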

Results

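Poly(A) RNA of mouse prefrontal cortex was counted per gene in 22 libraries from 3 mutant lines, each with wild-type (WT) libraries of its own line. The Tcf20+/- line (heterozygous for Tcf20, which encodes a nuclear co-regulator of transcription) had 3 mutant and 3 WT libraries. The Phf14+/- line (heterozygous for Phf14, which encodes a nuclear PHD finger protein) had 3 and 3. The MeCP2 KO line (knockout of Mecp2, which encodes the methyl-CpG binding protein mutated in Rett syndrome) had 5 and 5. The Tcf20+/- libraries held 47222944, 48856502 and 46230804 counts for replicates 1 to 3, and their WT libraries 35100485, 59654888 and 47210391. The Phf14+/- libraries held 66291968, 63684875 and 75887744 counts, and their WT libraries 44674032, 43794002 and 58910796. The MeCP2 KO libraries held 89551437, 98841952, 67983019, 104228305 and 109477891 counts for replicates 1 to 5, and their WT libraries 67872992, 51729007, 77686007, 77747326 and 89469453. Mitochondrially encoded genes took 3.18 to 5.13% of the counts of a library. Xist, the RNA that coats the inactive X chromosome, stayed at or below 0.171 CPM (counts scaled to a common library size) in every library, and the Y-linked Ddx3y lay between 35.1 and 58 CPM.

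The targeted genes were read first, as a check of the labels. Mecp2 was at 6.93 CPM ± 0.812 (SD, n = 5) in MeCP2 KO and at 119 ± 22.5 (n = 5) in WT, which is 5.82% of the WT level, and the highest KO library, at 7.82, lay below the lowest WT library, at 87.8. Its log2 fold change was -4.10 (SE 0.136), with an adjusted p of 9.61e-10 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Tcf20 was at 117 ± 2.76 CPM in Tcf20+/- (n = 3) and 127 ± 3.99 in WT (n = 3), 92% of the WT level, with a log2 fold change of -0.12 (SE 0.0532). The 3 Tcf20+/- values, 115 to 120 CPM, lay below the 3 WT values, 123 to 130. The edgeR p was 0.0424 unadjusted and 0.853 adjusted over all tested genes, with a 95% interval of the log2 fold change from -0.268 to 0.0278. The interval takes its degrees of freedom from the line's libraries alone, and is wider than the edgeR test implies. Phf14 was at 50.9 ± 3.27 CPM in Phf14+/- and 50.4 ± 5.85 in WT (n = 3 each), 101% of the WT level, with an edgeR adjusted p of 0.976 and a 95% interval of the log2 fold change from -0.21 to 0.24. The labels do not describe the mutant alleles, and whether counted reads come from an undeleted part or a label is wrong is unknown, so Tcf20+/- and Phf14+/- stand for the libraries labelled so wherever a direction is given. Mecp2 lies on chromosome X from 74026592 to 74135363, Tcf20 on chromosome 15 from 82808436 to 82987872 and Phf14 on chromosome 6 from 11907809 to 12081205 (GRCm38 in the reference annotation).

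**Figure D1:**
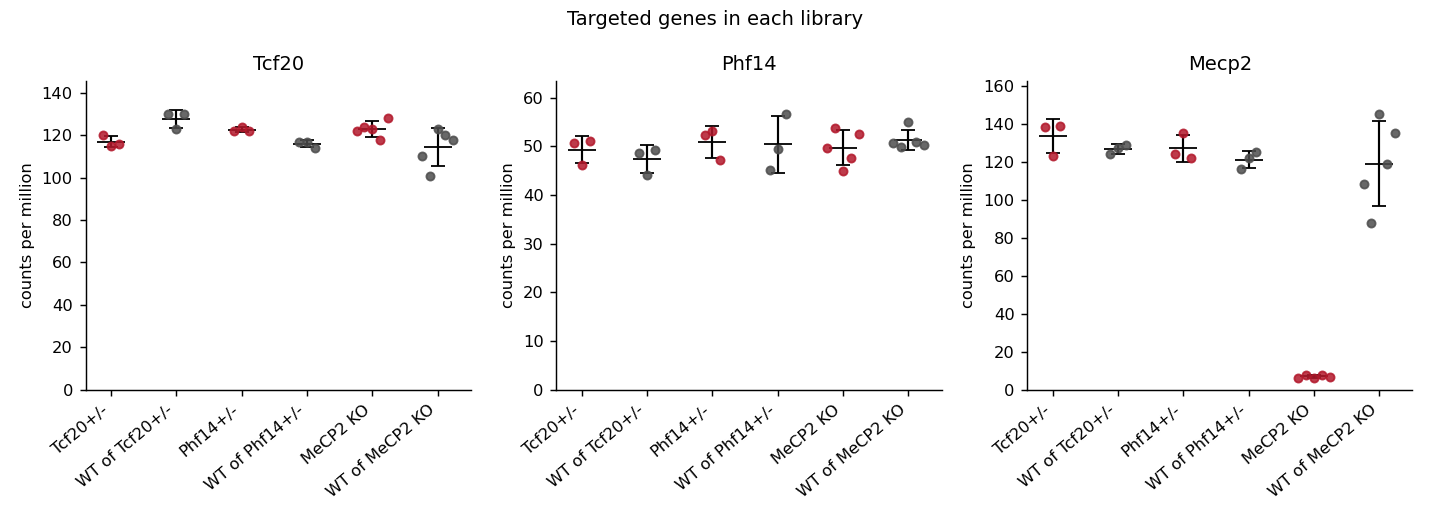
CPM of Tcf20, Phf14 and Mecp2 in all 22 libraries, grouped by line and genotype, with points for libraries and bars for the mean and SD. Mecp2 sits between 6.12 and 7.82 in the 5 MeCP2 KO libraries and between 87.8 and 145 in their WT, while Tcf20 and Phf14 stay near their WT level in the lines named after them.

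The first comparison asked which genes change in prefrontal cortex without MeCP2, a protein that binds methylated DNA and recruits co-repressors. In MeCP2 KO (n = 5) against WT (n = 5), 864 genes rose and 797 fell among 20096 tested. Among the genes with the largest rises, Irak1, a kinase of interleukin-1 receptor signalling encoded beside Mecp2, went from 45.9 ± 1.67 to 95.2 ± 3.85 CPM (log2 fold change 1.05, SE 0.0532). Rora, a nuclear receptor, went from 74.2 ± 11.1 to 149 ± 19.3 CPM (log2 1.01, SE 0.108), and Cabp7, a calcium-binding protein, from 13 ± 1.89 to 30.2 ± 1.52 CPM (log2 1.22, SE 0.0934). Among those with the largest falls, Tnnc1, the slow troponin C, fell by 1.96 on the log2 scale (SE 0.0928), from 16 ± 1.53 to 4.11 ± 0.423 CPM, and Grp, gastrin-releasing peptide, fell by 1.79 (SE 0.104), from 6.24 ± 0.792 to 1.80 ± 0.113 CPM.

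The other large rises were in Clcnka (a chloride channel, log2 1.42), Bmper (a secreted binder of bone morphogenetic proteins, 1.09), Dlk1 (an imprinted transmembrane ligand, 1.09), the collagen-binding integrin gene Itga11 (1.03), the collagen gene Col5a1 (1.02), Fam83d (1.02) and Proser2 (0.96). The other large falls were in Aldh1a3 (an enzyme of retinoic acid synthesis, -3.13), Pappa2 (a protease of IGF binding proteins, -2.18), AW551984 (-2.16), Ngb (neuroglobin, -1.75), Postn (a matrix protein, -1.64), Aldh3b2 (-1.60) and Crlf1 (a secreted cytokine partner, -1.46). Their adjusted p in edgeR with Benjamini-Hochberg adjustment ran from 6.16e-08 for Tnnc1 to 0.00808 for Fam83d. Of the 1661 called genes, 1510 were protein-coding, 501 changed at least 1.5-fold and 161 at least 2-fold, and the median size of their log2 change was 0.43. The 2 groups did not overlap at 9.77% of all tested genes, where chance gives 0.794%. An unadjusted p under 0.05 was reached by 5149 genes.

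**Figure D2:**
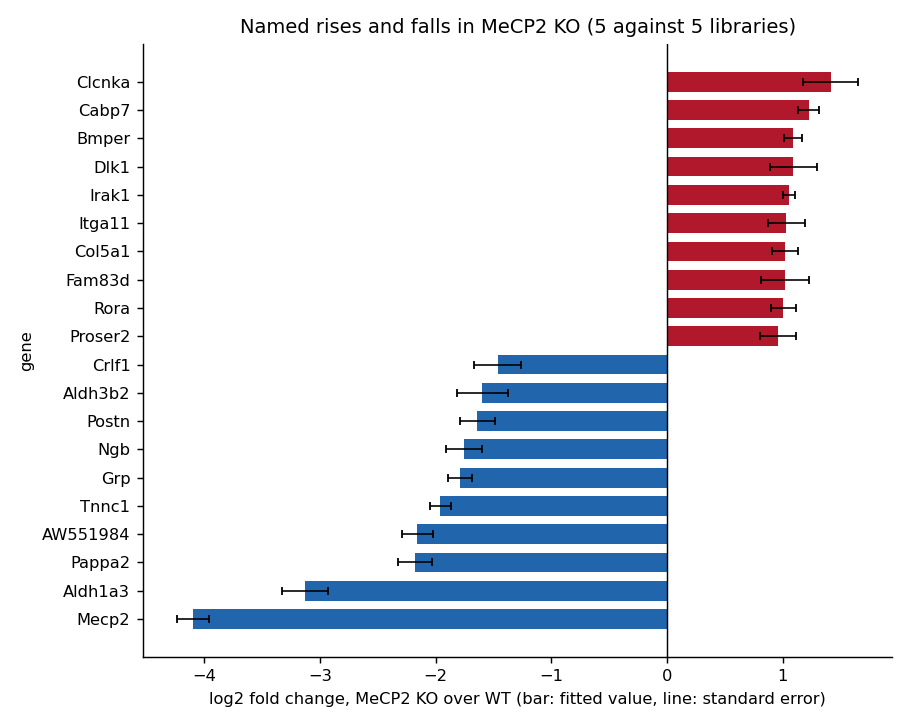
Log2 fold changes of the genes with the largest rises and falls in MeCP2 KO against WT (n = 5 each), with bars for the standard error. Mecp2 has the largest fall, at -4.10, and Clcnka the largest rise, at 1.42.

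The count of 1661 depended on single libraries and on the tool. It was 965 without MeCP2 KO replicate 2, 1029 without KO replicate 5, 1052 without WT replicate 1 and 3600 without WT replicate 3, and it was 2512 with DESeq2 and 3935 with limma voom.

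Neuropeptide genes as a group were lower in MeCP2 KO. Of 22 members, 12 fell and none rose over all genes tested (15 fell adjusted over the list alone), with a median log2 fold change of -0.41. Tac2, which encodes neurokinin B, fell by 1.39 (3.54 ± 0.62 against 9.30 ± 1.32 CPM, edgeR adjusted p = 2.95e-05), and Crh, corticotropin-releasing hormone, fell by 1.07 (3.27 ± 0.354 against 6.86 ± 0.516 CPM). Pdyn, prodynorphin, fell by 0.60 and Vip, vasoactive intestinal peptide, by 0.42. The list mean was 4.13 ± 0.039 in KO and 4.55 ± 0.172 in WT on the log2 CPM scale, with an exact permutation p of 0.00794, the smallest that 5 against 5 allows. Against other genes the list was lower by limma's camera (adjusted p = 2.66e-09), and adjusted p = 0.733 with an estimated correlation. Interneuron markers, several of which are these peptides, held 5 members that fell among 18 (6 fell and 1 rose over the list alone), including Calb2 (fell by 1.02), Tac1 (fell by 0.85) and the serotonin receptor gene Htr3a (fell by 0.43), with a camera adjusted p of 0.189 and an exact permutation p of 0.0159 for the list mean.

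Genes that respond to glucocorticoids were higher. Of 17 measured members, 6 rose and none fell (8 rose adjusted over the list alone), with a median log2 fold change of 0.35. Sgk1, a kinase induced by the hormone, was at 91.9 ± 25.2 CPM in KO against 52 ± 5.15 in WT (log2 0.82, edgeR adjusted p = 0.00674), and Fkbp5, a chaperone of the glucocorticoid receptor, was at 51 ± 15 against 29.7 ± 2.78 CPM (log2 0.78). Pdk4 (0.56) and Tsc22d3 (0.58) rose too, and lost the call in 1 and 7 of 19 refits. The list mean varied more among the KO libraries, from 4.31 to 5.16, than among the WT libraries, from 4.25 to 4.40, with an exact permutation p of 0.0317. Camera gave an adjusted p of 2.49e-04, and adjusted p = 0.733 with an estimated correlation.

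Axon guidance and adhesion genes held 13 rises and 2 falls among 51 members (19 rises and 3 falls over the list alone), with a median log2 fold change of 0.20. Unc5d, a netrin receptor, rose by 0.58 on the log2 scale (SE 0.0814), the protocadherin gene Pcdh9 by 0.49, and the netrin genes Ntng1 and Ntn4 by 0.37 and 0.35. The list was higher by camera (adjusted p = 3.7e-06), and adjusted p = 0.733 with an estimated correlation. Among 39 voltage-gated ion channel genes, 7 rose and 3 fell (12 and 3 over the list alone). The sodium channel gene Scn1a rose by 0.58 and the potassium channel gene Kcnd2 by 0.37, while the auxiliary subunit genes Scn3b and Kcnip2 fell by 0.59 and 0.52. Camera gave that list a higher direction with an adjusted p of 0.00233, and adjusted p = 0.733 with an estimated correlation. Of 38 autism and intellectual disability genes, Auts2 (log2 0.55), Cntnap2 (0.32) and Foxp1 (0.30) rose, and 6 rose over the list alone. Cntnap2 and Foxp1 each lost the call in 9 of 19 refits, and Auts2 in 0. That list was higher by camera (adjusted p = 1.14e-04), and adjusted p = 0.733 with an estimated correlation. For these 3 lists the lowest library means were those of WT replicates 1 and 2, at 5.31 and 5.16 for axon guidance, 7.02 and 6.85 for ion channels and 6.42 and 6.24 for autism genes. Without these 2 libraries the ion channel and autism lists were no longer called, with median differences in log2 CPM of 0.0654 (camera adjusted p = 0.282) and 0.0236 (0.322). The axon guidance list kept its call in all 13 refits, with a median difference in log2 CPM as low as 0.0626.

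Protein folding genes were lower, with 4 falls and no rise among 24 members (5 falls over the list alone) and a median of -0.13. The endoplasmic reticulum chaperone gene Calr fell by 0.32, the disulfide isomerase genes Pdia6 and Pdia3 by 0.27 and 0.23, and the mitochondrial co-chaperone gene Hspe1 by 0.35. Camera gave an adjusted p of 3.14e-04, and adjusted p = 0.733 with an estimated correlation. Ribosomal protein genes had a median of -0.23 with 78 of 80 members below 0, and nuclear oxidative phosphorylation genes a median of -0.16 with 81 of 86 below 0. In neither list did a member pass the edgeR test, over all genes or over the list alone, and the smallest adjusted p were 0.0679 for Rps28 and 0.0584 for Atp5k. Camera gave adjusted p of 1.33e-09 and 6.43e-05 for these 2 lists, and adjusted p = 0.733 and adjusted p = 0.851 with an estimated correlation. WT replicates 1 and 2 had the highest library means of both lists, at 6.45 and 6.58 for ribosomal proteins, where the other libraries lay between 5.97 and 6.18. Without these 2 libraries neither list was called by camera. The median difference in log2 CPM was then -0.0342 for ribosomal proteins (adjusted p = 0.139) and 0.0356 for oxidative phosphorylation genes (adjusted p = 0.309, direction turned), and camera called the glutamatergic, GABAergic and striatal lists instead. Mitochondrially encoded genes had a median of -0.16 over 14 members, none past the test (camera adjusted p = 0.0157, and adjusted p = 0.733 with an estimated correlation), and lost their call in 4 of 13 refits.

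Lists of microglial, myelin and blood markers were also called by camera at its preset correlation. Microglial markers held 5 falls among 16 members (8 over the list alone), including Fcrls (fell by 0.56), Aif1 (fell by 0.41) and the complement genes C1qb and C1qa (fell by 0.39 and 0.36). Their list mean was 4.37 ± 0.0488 in KO and 4.59 ± 0.119 in WT (exact permutation p = 0.00794), with a camera adjusted p of 6.43e-05, and adjusted p = 0.733 with an estimated correlation. All 16 myelin and oligodendrocyte markers lay above 0 with a median of 0.29, and Hapln2, a matrix protein of nodes of Ranvier, rose by 0.58 and passed alone. Their list mean was 6.60 ± 0.122 against 6.27 ± 0.36, with WT replicate 3 at 5.64 and the other WT libraries between 6.28 and 6.52 (camera adjusted p = 7.35e-05, and adjusted p = 0.733 with an estimated correlation). All 5 measured blood markers lay above 0, of which Alas2 (log2 0.67) and Hbb-bt (0.75) rose and all 5 rose over the list alone. Globin genes share near-identical copies, so their single values are uncertain (camera adjusted p = 0.00108, and adjusted p = 0.733 with an estimated correlation).

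The remaining lists were not called by camera in MeCP2 KO, although single members were. Among upper cortical layer markers the calcium-binding protein gene Calb1 fell by 0.64 and Wfs1 by 0.69, Otof fell by 0.64 and Cux1 rose by 0.30, with 9 of 13 members above 0 and 4 rises and 3 falls over the list alone. Among deep layer markers Crym fell by 0.60, Nxph4 by 0.75 and Syt6 by 0.24, and Parm1 rose by 0.39, where Syt6 lost its call in 13 of 19 refits and Nxph4 in 9, with 3 rises and 3 falls over the list alone. Of the presynaptic genes Vamp1 (0.55), Syt2 (0.61) and Sv2c (0.52) rose and Rab3b fell by 0.32, with a list mean of 8.613 ± 0.0237 against 8.519 ± 0.0781 log2 CPM (exact permutation p = 0.00794). Of 22 GABAergic synapse genes 4 receptor subunit genes fell, Gabra5 by 0.43, Gabrg1 by 0.28, Gabra2 by 0.25 and Gabra3 by 0.22. In the glutamatergic list Cacng8 fell by 0.37, Grik5 by 0.28 and Dlg4 by 0.21, and Slc17a6 rose by 0.48. Of 19 refits, Dlg4 and Slc17a6 each lost the call in 7, Grik5 in 8 and Cacng8 in 0. In the list of genes linked to Mecp2 in earlier studies 3 rose and 4 fell, Crh among them. Olfactory bulb markers held 1 rise (Pbx3, 0.49) and 4 falls, Th among them (fell by 0.83), and their list mean was 2.29 ± 0.103 against 2.52 ± 0.179 (exact permutation p = 0.0476).

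Smaller numbers passed in the last lists. Fosl2 rose by 0.85 among 24 activity-regulated genes, whose list mean ran from 5.23 to 6.04 in KO libraries and from 5.27 to 5.71 in WT. Among cholesterol synthesis genes Fdps (low counts, shared with pseudogenes) fell by 0.51, Hmgcs1 fell by 0.26 and Ldlr rose by 0.35. C1ql1 fell by 0.55 among oligodendrocyte precursor markers, and Vtn fell by 0.37 and Notch3 rose by 0.39 among mural markers. Igfbp2 fell by 0.57 among meningeal markers, and Rarb rose by 0.33 and Gng7 fell by 0.30 among striatal markers. In the list of the TCF20 complex and NCoR co-repressor, Mecp2 was the member past the test over all genes. No astrocyte, endothelial, choroid plexus or interferon response gene of the lists passed, with smallest adjusted p of 0.0585 for Gjb6, 0.1 for Flt1, 0.163 for Kl and 0.0647 for C3. Camera adjusted p of the uncalled lists ran from 0.0737 for olfactory bulb markers to 0.941 for genes linked to Mecp2. Mean and camera direction differed in sign for the TCF20 complex (mean -0.30, which Mecp2 sets) and for genes linked to Mecp2, striatal, upper layer and deep layer markers, and median and mean differed for meningeal markers.

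**Figure D3:**
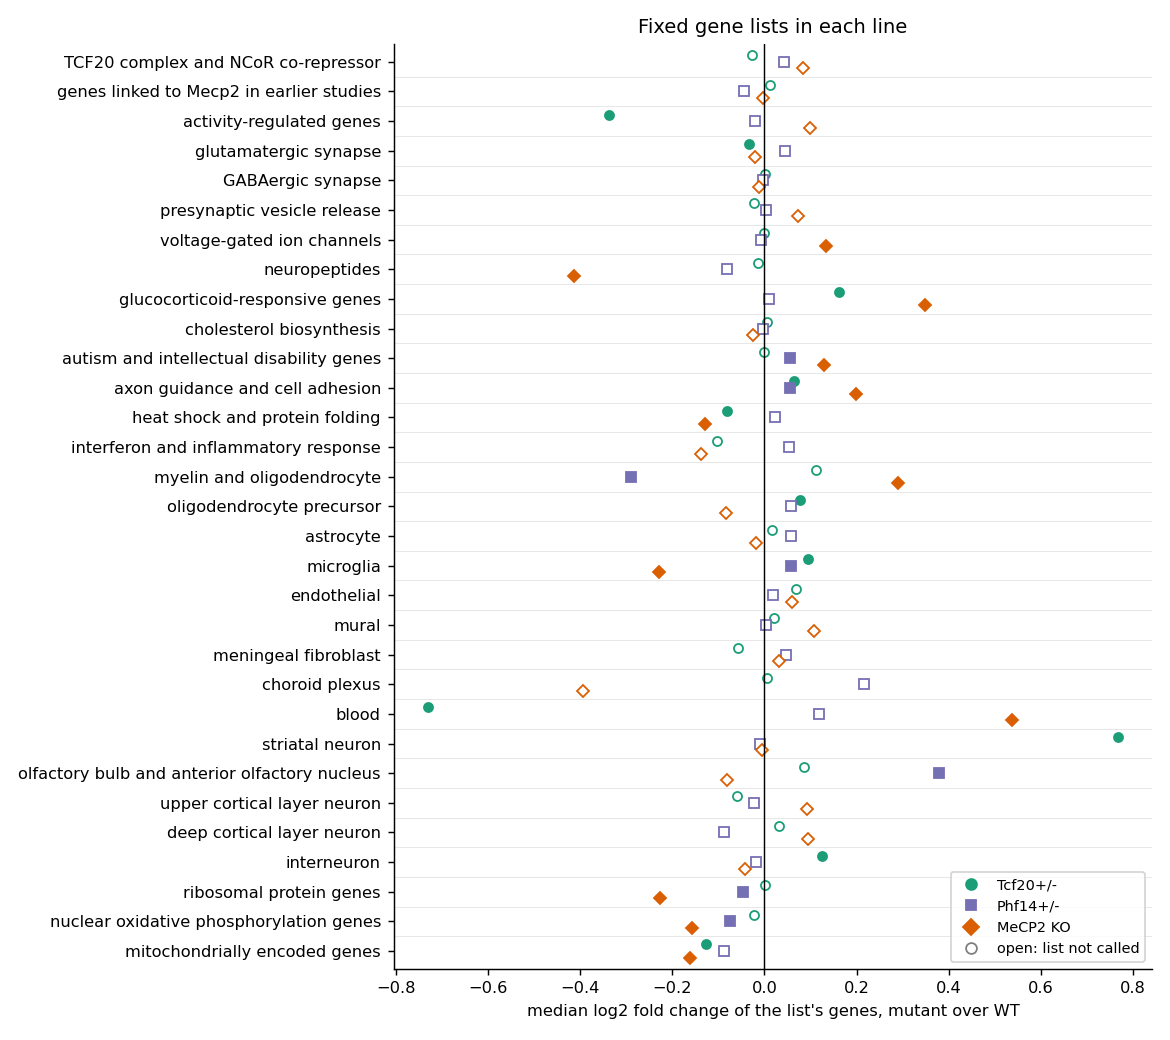
Median log2 fold change of the members of each of the 31 fixed gene lists in the 3 lines, mutant against WT, with filled points for lists called by camera at its preset correlation. The neuropeptide list sits at -0.41 in MeCP2 KO, the activity-regulated list at -0.34 and the striatal list at 0.77 in Tcf20+/-, and the myelin list at -0.29 in Phf14+/-.

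The same comparison was made for the libraries labelled Tcf20+/-. Bhlhe40, a clock-linked transcriptional repressor, fell by 0.52 on the log2 scale (SE 0.0637), from 170 ± 10.2 CPM in WT (n = 3) to 119 ± 7.07 in Tcf20+/- (n = 3), with an edgeR adjusted p of 0.0407. It was the 1 gene past the threshold of 18587 tested, and 1079 reached an unadjusted p under 0.05. Bhlhe40 is also induced by neuronal activity, and the list of activity-regulated genes was lower by camera, though with 0 members called, adjusted p = 0.379 with an estimated correlation and an exact permutation p of 0.2. The next smallest p belonged to Cbln2, a synaptic organizer (log2 -0.37, edgeR adjusted p = 0.132), the protocadherin gene Pcdh11x (0.43, 0.132), Trib2 (-0.38, 0.132), Ier5, an immediate early gene (-0.40, 0.132) and Dusp4, a MAP kinase phosphatase (-0.64, 0.132). Dnajb5 (-0.33) and Midn (-0.42) followed with adjusted p of 0.161, as did Sgk1 (0.40), and the receptor gene Ephb3 (-0.32) had 0.185.

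The groups did not overlap at 10.4% of genes, where chance gives 10%. DESeq2 called 46 genes and limma voom 13. The count was 10, 0 and 18 without Tcf20+/- replicates 1, 2 and 3, and 0, 58 and 0 without WT replicates 1, 2 and 3. Bhlhe40 was in the calls of those refits that called any gene. With the striatal marker mean as a covariate 2 genes were called and Bhlhe40 was not among them, and over all settings it lost its call in 6 of 15. Its log2 fold change lay between -0.5645 and -0.4046 in these 15 settings.

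Activity-regulated genes, which neurons switch on within minutes to hours of firing, had a median of -0.34 in Tcf20+/-, with 22 of 24 members below 0. None passed over all genes tested, and 11 fell adjusted over the list alone. Among them were Egr1 (253 against 361 CPM, log2 -0.51), Fos (19.6 against 35.2, -0.84), Bdnf, a neurotrophin (23.6 against 32, -0.44), Dusp6 (72.5 against 95.2, -0.39) and Per1 (111 against 137, -0.31). The list was lower by limma's camera (adjusted p = 5.97e-20), and adjusted p = 0.379 with an estimated correlation. The library means were 5.28, 5.33 and 5.45 in Tcf20+/- and 5.84, 5.43 and 5.88 in WT, so WT replicate 2 lay within the range of the mutants (exact permutation p = 0.2). In the same libraries the striatal marker mean was 5.47, 5.02 and 4.14 in Tcf20+/- against 3.96, 3.9 and 3.88 in WT.

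Striatal markers had a median of 0.77, with all 11 measured members above 0. Adora2a, the adenosine receptor of striatopallidal neurons, was at 13.5 CPM against 2.37 (log2 2.49) and the dopamine receptor gene Drd2 at 7.996 against 1.76 (2.19), and 3 members rose over the list alone (Gpr6, Pde10a and Rarb). Replicates 1 and 2 carried these means, with Adora2a at 22.8, 14.2 and 3.31 CPM and Drd2 at 13.4, 8.32 and 2.25 in Tcf20+/- replicates 1 to 3. Without replicates 1 and 2 the median difference of the list in log2 CPM went from 0.68 to 0.135 (camera adjusted p = 0.00864). Camera gave an adjusted p of 2.75e-15, and adjusted p = 0.396 with an estimated correlation. Interneuron markers, some of which striatal neurons also express, had a median of 0.13 (camera adjusted p = 2.66e-05, and adjusted p = 0.379 with an estimated correlation), and Gad2, an enzyme of GABA synthesis, was at 160 ± 18 against 132 ± 3.96 CPM. All 5 blood markers lay below 0 with a median of -0.73 and all 5 fell over the list alone, with library means of 2.12 to 2.54 against 2.92 to 3.37. Camera gave that list an adjusted p of 2.6e-11, and adjusted p = 0.379 with an estimated correlation.

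Other lists had smaller medians in Tcf20+/-. Heat shock and folding genes had a median of -0.08, with 20 of 24 below 0 and Dnajb5 past the test over the list alone (camera adjusted p = 6.72e-06, and adjusted p = 0.524 with an estimated correlation). Axon guidance genes had a median of 0.06, with 43 of 51 above 0 (camera adjusted p = 4.42e-04, and adjusted p = 0.605 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.16, with 4 rises and 1 fall over the list alone (camera adjusted p = 0.00867, and adjusted p = 0.524 with an estimated correlation). Mitochondrially encoded genes had a median of -0.13 and 5 falls over the list alone, among which mt-Atp6 and mt-Co2 share reads with nuclear copies (camera adjusted p = 7.75e-06, and adjusted p = 0.539 with an estimated correlation). Microglial markers had a median of 0.09 (camera adjusted p = 0.00223, and adjusted p = 0.843 with an estimated correlation) and oligodendrocyte precursor markers 0.08, with 1 rise over the list alone, Vcan (camera adjusted p = 0.0226, and adjusted p = 0.958 with an estimated correlation). The precursor list lost its call in 3 of 9 refits, and its direction turned without Tcf20+/- replicate 1 and without replicates 1 and 2. The microglial list lost its call in 4 of 9, with median differences in log2 CPM from -0.0263 to 0.168. Glutamatergic synapse genes had a median of -0.03, with Homer1, a scaffold gene that is also activity-regulated, past the test over the list alone (camera adjusted p = 0.0397, and adjusted p = 0.634 with an estimated correlation).

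Camera did not call the other 20 lists in this line, with adjusted p from 0.0938 for interferon response and for oxidative phosphorylation genes to 0.932 for mural markers. They were the TCF20 complex, genes linked to Mecp2, GABAergic synapse, presynaptic, ion channel, neuropeptide, cholesterol and autism genes, ribosomal proteins, and markers of myelin, astrocytes, endothelium, meninges, choroid plexus, olfactory bulb and upper and deep cortical layers. Over the list alone, Sgk1 was among 2 rises and Crh (5.04 ± 0.431 against 7.22 ± 0.331 CPM) among 2 falls of genes linked to Mecp2. Means and camera directions differed in sign for neuropeptides, genes linked to Mecp2, presynaptic genes, ion channels, mural markers and ribosomal proteins, whose medians lay between -0.02 and 0.02. Deep layer markers had a median of 0.03, a mean of -0.01 and a lower direction by camera.

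The same comparison was made for the libraries labelled Phf14+/-, in which Phf14 RNA was not lower. Fn1, which encodes the matrix protein fibronectin, rose by 0.44 on the log2 scale (SE 0.0525), from 60.2 ± 2.03 CPM in WT (n = 3) to 81.5 ± 2.09 in Phf14+/- (n = 3), with an edgeR adjusted p of 0.0302, and was no longer called in 7 of 14 refits, with the same direction in each. Gm43305, a predicted gene with no known function, fell by 4.71 (SE 0.337), from 3.49 ± 0.825 to 0.127 ± 0.0913 CPM, with an adjusted p of 2.67e-04, and stayed called in each refit. These were the 2 genes past the threshold of 19191, and 1762 reached an unadjusted p under 0.05. In simulated counts of this line with no gene changed edgeR called 4 genes. Tnnc1, which fell in MeCP2 KO, was at 32.8 ± 0.252 against 22.9 ± 2.12 CPM here (log2 0.52, edgeR adjusted p = 0.0542), and Rspo1, a secreted activator of Wnt signalling, at 4.76 ± 0.508 against 9.58 ± 1.91 (0.0542).

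Gm9522 had 0 counts in the 3 Phf14+/- libraries and 36 in WT (0.244 CPM), at least 16.8-fold lower by a floor of 3 counts over the group (0.0146 CPM), with an edgeR adjusted p of 0.0676. Capn11, a calpain protease gene, was at 5.49 ± 2.59 against 0.225 ± 0.0631 CPM (log2 4.64, edgeR adjusted p = 0.101). Adjusted p of 0.124 to 0.151 belonged to Hk2, a hexokinase gene (log2 0.55), Sik2 (0.42), the collagen gene Col6a2 (0.37) and Gm765 (-0.85). The groups did not overlap at 15.4% of genes, where chance gives 10%. DESeq2 called 69 genes and limma voom 6. The count was 7, 1 and 6 without Phf14+/- replicates 1, 2 and 3, and 2, 1 and 6 without WT replicates 1, 2 and 3.

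Myelin and oligodendrocyte markers were lower in Phf14+/-, with all 16 members below 0 and a median of -0.29. The list mean was 5.996 ± 0.197 against 6.288 ± 0.203 log2 CPM (exact permutation p = 0.2), and the groups overlapped, with Phf14+/- replicate 1 at 6.2146 and WT replicate 2 at 6.0539. None passed over all genes, and 10 fell over the list alone, among them the myelin protein genes Mbp (1659 ± 238 against 2090 ± 276 CPM, log2 -0.33) and Plp1 (970 against 1187 CPM, -0.29). Camera gave an adjusted p of 8.44e-11, and adjusted p = 0.605 with an estimated correlation. Nuclear oxidative phosphorylation genes had a median of -0.07, with 77 of 84 below 0, and Cox5a, a cytochrome oxidase subunit gene, was at 45.2 ± 4.01 against 58.1 ± 6.31 CPM. Camera gave them an adjusted p of 8.44e-11, and adjusted p = 0.605 with an estimated correlation. Ribosomal protein genes had a median of -0.05, with 70 of 79 below 0 (camera adjusted p = 1.54e-04, and adjusted p = 0.605 with an estimated correlation).

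Olfactory bulb markers had a median of 0.38, and their library means were 2.41, 3.77 and 2.30 in Phf14+/- against 2.26, 2.26 and 2.45 in WT, so the difference lay in Phf14+/- replicate 2 (camera adjusted p = 0.0171, and adjusted p = 0.755 with an estimated correlation). Axon guidance genes had a median of 0.06 with 3 rises and 1 fall over the list alone, Slit1 at 83.7 ± 2.48 against 72 ± 2.77 CPM and Efna5 at 19.2 ± 0.38 against 22.6 ± 0.594 (camera adjusted p = 0.0171, and adjusted p = 0.755 with an estimated correlation). Autism and intellectual disability genes had a median of 0.06, with Kmt2a, a histone methyltransferase gene, past the test over the list alone (camera adjusted p = 0.0171, and adjusted p = 0.605 with an estimated correlation). Microglial markers had a median of 0.06 (camera adjusted p = 0.0312, and adjusted p = 0.605 with an estimated correlation). Microglial markers lost the call in 5 of 8 refits and the axon guidance and autism lists in 4 each. Camera did not call the other 24 lists, with adjusted p from 0.0533 for glutamatergic synapse genes to 0.977 for striatal markers, and activity-regulated genes had a median of -0.02. Genes past the test over the list alone included Pde10a among striatal markers, Pdyn among neuropeptides, Syn3 among presynaptic genes, Kdr among endothelial and Otof among upper layer markers. Median or mean differed in sign from the camera direction for oligodendrocyte precursor, mural, striatal, upper layer and interneuron markers and for ion channel genes, all with medians between -0.02 and 0.06.

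**Figure D4:**
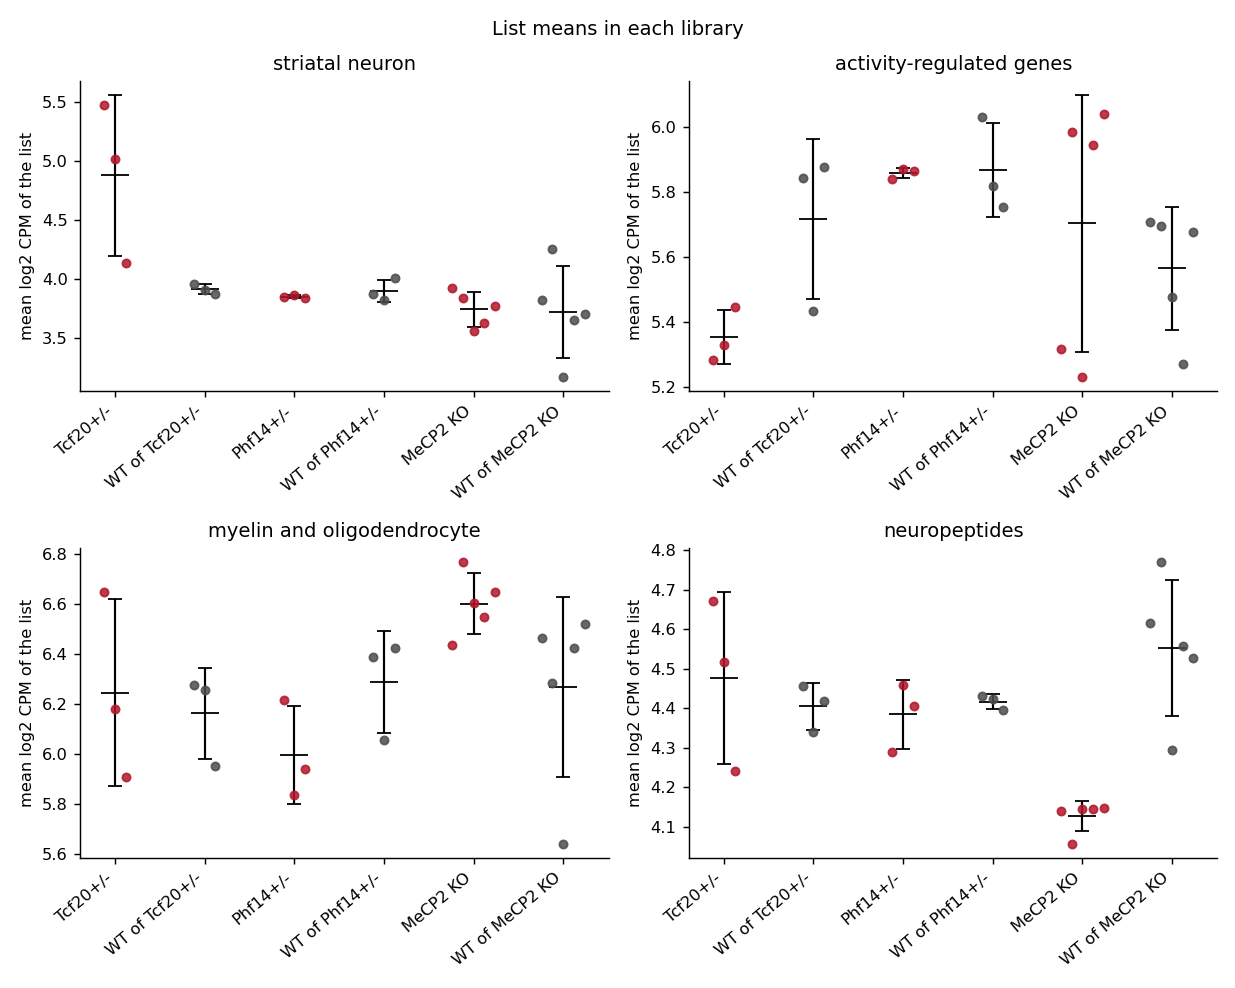
Mean log2 CPM of 4 gene lists in single libraries, by line and genotype, with bars for the group mean and SD and axes that do not start at 0. Tcf20+/- replicates 1 and 2 carry the highest striatal means, 5.47 and 5.02, and WT replicate 3 of the MeCP2 line the lowest myelin mean, 5.64.

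The title of the series names a complex of MeCP2 and TCF20, which raises the question whether the 3 lines move the same genes the same way. Across genes the log2 fold changes had Pearson r of 0.0533 for MeCP2 KO and Tcf20+/- (18381 genes, Spearman rho 0.0886), 0.0746 for MeCP2 KO and Phf14+/- (18823 genes, rho 0.125) and -0.00211 for Tcf20+/- and Phf14+/- (18467 genes, rho 0.0385, of the other sign). Genes are not independent replicates, so p came from two-sided exact permutation of the genotype labels, at 0.567, 0.45 and 0.99, adjusted to 0.85, 0.85 and 0.99 over the 3 pairs. No gene was called by edgeR in more than 1 line of the 18290 tested in all 3. With 1 and 2 genes called in Tcf20+/- and Phf14+/-, at most 0.0884 shared calls were expected by chance for a pair, so this says little. At an unadjusted p under 0.05, 391 genes were shared by MeCP2 KO and Tcf20+/-, where 282.9 were expected, and 257 of them had the same direction. For MeCP2 KO and Phf14+/- the overlap was 588 against 459.3 (343 in the same direction). For Tcf20+/- and Phf14+/- it was 161 against 98.9 (75 in the same direction). The expected counts assume that passing in 1 line is independent of passing in the other, and labels were not permuted for them. The odds ratio was highest for Tcf20+/- and Phf14+/- (1.82, against 1.66 and 1.48), although r was -0.00211 there. An excess over these counts therefore does not show that lines move genes alike. The r of MeCP2 KO and Tcf20+/- was -0.0416 without Tcf20+/- replicate 3 and -0.0263 without WT replicate 1 of that line in the correlation of log2 fold changes, MeCP2 KO and Tcf20+/-.

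The genes called in MeCP2 KO were then tested as 2 sets in the other lines. The genes that rose in MeCP2 KO had a mean log2 fold change of 0.0412 in Tcf20+/- (855 genes, 63.6% above 0, camera adjusted p = 0.00538, and p = 0.351 with an estimated correlation). The genes that fell had a mean of 0.0203 and a median of -0.00122 there, with a lower direction by camera, so mean and test differed in sign (770 genes, adjusted p = 0.852). In Phf14+/- the genes that rose in MeCP2 KO had a mean of 0.00703 (858 genes, camera adjusted p = 0.225). The genes that fell in MeCP2 KO were higher in Phf14+/-, with a mean of 0.0439 (775 genes, 57.3% above 0, camera adjusted p = 0.0211, and p = 0.233 with an estimated correlation), and Tnnc1 is one of them. For MeCP2 KO gene sets in Tcf20+/-: genes higher in MeCP2 KO, adjusted p was 0.162, 0.225 and 0.0625 without Tcf20+/- replicate 3, WT replicate 1 and WT replicate 3. For MeCP2 KO gene sets in Phf14+/-: genes lower in MeCP2 KO, it was 0.0825, 0.137 and 0.143 without Phf14+/- replicates 2 and 3 and WT replicate 1.

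Whether a gene's change differed between lines was tested as an interaction in 1 edgeR fit of all 22 libraries, over 21171 genes. That fit shares 1 estimate of the spread per gene. The common coefficient of variation was 11.7% in the MeCP2 line, 7.85% in the Tcf20+/- line and 6.73% in the Phf14+/- line. In the shared fit MeCP2 KO against WT had 3335 calls, where its own fit had 1661, so the interaction counts with MeCP2 KO may be too high. Between MeCP2 KO and Tcf20+/- 420 genes differed, 158 higher and 262 lower in MeCP2 KO, and between MeCP2 KO and Phf14+/- 512 differed, 218 higher and 294 lower. Irak1 differed by 1.09 (SE 0.0778) and 1.00 (SE 0.0776) in these 2 tests, Tnnc1 by -1.86 and -2.48, and Pdyn by -0.71 and -0.89, with edgeR adjusted p of 5.11e-05 and below. Auts2 differed by 0.72 and 0.47, with adjusted p of 6.98e-05 and 0.00566. Against Tcf20+/- the activity-regulated Fosl2 (1.253), the phosphatase gene Dusp4 (1.47) and the synaptic organizer gene Cbln2 (0.71) also differed, as did the blood marker Alas2 (1.30), with edgeR adjusted p of 0.00913, 0.0024, 1.67e-04 and 0.00243. Between Tcf20+/- and Phf14+/- 2 genes differed, Gm43305 (5.41, SE 0.406) and Capn11 (-5.87, SE 0.552). An unadjusted p under 0.05 was reached by 3043, 2917 and 899 genes in the 3 tests. The MeCP2 line is an N129/FVB hybrid and the other lines C57BL/6, so these differences are also differences between strains and litters. The tests with MeCP2 KO also set a knockout, with Mecp2 at 5.82% of WT, against heterozygotes, with Tcf20 at 92% and Phf14 at 101% of WT. Neither these tests nor the correlations can therefore tell whether loss of each gene acts alike.

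The interaction counts moved with single libraries. The number of genes whose change differs between MeCP2 KO and Tcf20+/- was 218 and 205 without Tcf20+/- replicates 1 and 2, 259 and 260 without WT replicates 1 and 2 of that line, and 836 without WT replicate 3 of the MeCP2 line. It was 42 without both Tcf20+/- replicates 1 and 2, the libraries with high striatal markers, which leaves 1 Tcf20+/- library. The number of genes whose change differs between MeCP2 KO and Phf14+/- was 293 and 304 without Phf14+/- replicates 2 and 3, and 257, 340 and 303 without WT replicates 1, 2 and 3 of that line. The number of genes whose change differs between Tcf20+/- and Phf14+/- was 6 without Tcf20+/- replicate 1.

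Long genes, a class long studied in MeCP2 loss, were higher in MeCP2 KO. A length trend can also be a technical bias of RNA-seq, which was not tested. The trend was also not refitted without both WT replicates 1 and 2, whose list means stood apart. The median log2 fold change was 0.13 for 2470 genes over 100 kb and -0.02 for shorter genes. The difference of 0.15 had a two-sided exact permutation p of 0.0397 (5 of 126 splits as large). Of the 2470 long genes 428 were called, rises and falls together, where 1661 of all 20096 tested genes were called. Auts2, Rora, Unc5d, Pcdh9 and Cntnap2 are long genes that rose. The same difference was 0.02 in Tcf20+/- (exact p = 0.4) and 0.04 in Phf14+/- (exact p = 0.2), where 3 against 3 allows no p below 0.1. For gene length and fold change in MeCP2 KO, exact p was 0.0794, 0.103, 0.0635 and 0.111 without KO replicates 1, 2, 4 and 5, and 0.0556 and 0.0714 without WT replicates 1 and 2.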

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

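The tests of tissue from another region, of the state of single animals, of a strain variant and of a chromosome segment were chosen after the results were seen. The predictions for other splits of the samples were written before their results were seen. The equal-depth refits were added after the main results, with predictions written before any equal-depth value was seen.

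MeCP2 KO changed 1661 genes, and 100 splits of its 10 libraries, the real one among them, argue against chance, since only the real split (1 of 100) gave as many and the highest other gave 106. WT replicates 1 and 2 stood apart on the first principal component (35.6 and 59.7, where the other libraries lay at 13.7 or below), which might come from tissue of another region. Without them the log2 fold changes of the called genes kept a median of 0.885 of their size (interquartile range 0.763 to 1.01). For these genes that argues against such tissue as the whole cause. The 1661 genes were chosen with both libraries included, so the ratio covers only genes that passed with them. Without them 1117 genes were called, 972 of the 1661 among them, with fewer WT libraries to call with. At equal depth 1562 genes were called, which argues against the deeper KO libraries. Loss of MeCP2 stays as a hypothesis. Genes within 10 Mb of Mecp2 did not differ more often than others (17.7 against 25.7%, adjusted p = 0.237), and strain differences elsewhere in the genome were not tested.

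Activity-regulated genes were lower in Tcf20+/-, with a difference of -0.363 (SE 0.15) in the list mean. With the striatal marker mean as a covariate the difference was -0.247 (SE 0.26), smaller and with a wider error, so striatal tissue cannot be told apart from genotype with 3 libraries a group. The 3 WT libraries of the line themselves spanned 0.441, more than the difference between groups. A span of single libraries can exceed a difference of group means whatever its cause. It therefore cannot decide whether the state of single animals at collection accounts for the difference. Genotype also stays open, and the data hold no record of handling.

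In Phf14+/- Gm43305 and Gm9522 were nearly off and Capn11 on. Of these 3 genes, 1 (Capn11) also differed 20.4-fold between the WT libraries of the 2 C57BL/6 lines (4.58 ± 1.58 against 0.224 ± 0.0625 CPM), and Gm9522 differed without overlap too (0.0688 against 0.245 CPM, a ratio of 0.281, at few counts), as did Gm43305 (a ratio of 1.47). A strain variant that segregates in the colony could explain Capn11, and for Gm9522 and Gm43305 neither that nor the genotype is settled. Gm43305 was at 0 to 0.00957 CPM in MeCP2 KO and at 0 in its WT, so its level also differs between lines of different strain. A segment of strain origin around Phf14 is argued against, since 0 of the 3 genes lie on chromosome 6 with Phf14, but on chromosomes 14, 15 and 17. Depth is argued against too, since at equal depth the size of their log2 fold changes was 1.01 times that at full depth. That test was first run with the count filter, which left out Gm9522, and was rerun without the filter after that was seen.

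For the other results, the splits allow less. The count of 1 gene in Tcf20+/- was met by 2 of the 10 splits, and the highest other split, of Tcf20+/- replicate 1 with WT replicates 1 and 3, called 28 genes, which points to a structure of the samples other than genotype. The 2 genes in Phf14+/- were met by 1 of 10, with 0 genes in the highest other. Yet edgeR called 4 in simulated counts of that line with no gene changed, so Fn1 may be a false call. Its call was lost in 7 of 14 refits, but its log2 fold change stayed between 0.4172 and 0.4637, so the lost calls do not decide this. Gm43305 was called in each refit with adjusted p of 0.00343 or below. The 11 lists of Tcf20+/- and 7 of Phf14+/- were met by 8 and 5 of 10 splits, with highest others of 19 and 10. For the MeCP2 KO gene sets, values as the negative log10 of p were 2.57 and 0.0695 in Tcf20+/- (highest others 11.4 and 8.50, met by 4 and 9 of 10) and 0.649 and 1.98 in Phf14+/- (4.91 and 3.85, met by 6 and 3 of 10). With 10 splits no share under 0.05 can be reached. Chance cannot be excluded for the number of lists called in MeCP2 KO, 12, which 41 of 100 splits met, with 20 as the highest other. That count does not speak to single lists. The exact permutation p of the 12 list means ran from 0.00794 for neuropeptides and microglial markers to 0.302 for oxidative phosphorylation genes, unadjusted.

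Changes differed between lines by the interaction test, whose shared estimate of the spread may raise its counts. The 420 genes between MeCP2 KO and Tcf20+/- were met by 1 of 100 relabelings (highest other 1). The 512 between MeCP2 KO and Phf14+/- were met by 2 of 100 (highest other 528). Relabeling within both lines also removes the MeCP2 KO change itself. These shares thus argue against no change in either line, and cannot tell whether the 2 lines change differently. Leaving out 1 library moved the 420 to between 205 and 836. The 2 genes between Tcf20+/- and Phf14+/- were met by 5 of 100 (highest other 5), so chance cannot be excluded there.

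Single libraries of the MeCP2 line stood far from the other 4 of their group in 14 of 270 groups of values tested, where about 1 in 20 (13.5) is expected by chance. Among KO libraries, Aldh1a3 was at 0.299 CPM in replicate 5 (others 0.162 to 0.192), Pcdh9 at 160 in replicate 4 (189 to 198) and Gng7 at 76.4 in replicate 3 (82.2 to 84.6). The list mean of genes linked to Mecp2 was 5.58 log2 CPM in KO replicate 3 (5.72 to 5.76), of neuropeptides 4.06 in replicate 2 (4.14 to 4.15) and of blood markers 2.66 in replicate 1 (2.23 to 2.33). Among WT libraries, replicate 3 had Phf14 at 54.9 CPM (49.9 to 50.9), Folr1 at 0.179 (0.254 to 0.268), Otof at 38.3 (24.2 to 27.4) and a myelin list mean of 5.64 (6.28 to 6.52). WT replicate 2 had Hspe1 at 63.8 CPM (44 to 49.4), Notch3 at 8.88 (10.4 to 11), Parm1 at 67.4 (85.2 to 89.9) and an interferon list mean of 2.39 (1.91 to 2.04).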

How the results depend on the processing

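The equal-depth, marker-covariate and paired-removal settings were added after the main results were seen, and the others were chosen before the data.

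All 1661 genes of genes changed in MeCP2 KO against WT kept their direction in each refit, except that 1632 of them were tested at equal depth, all in the same direction. Their number was 2512 with DESeq2, 3935 with voom, 3335 in 1 fit of all libraries and 976 with a replicate block. It was 3939 with the striatal covariate, 1117 without WT replicates 1 and 2 and 2833 at an adjusted p under 0.1. Leaving out 1 library gave 965 to 3600. Genes changed in Tcf20+/- against WT numbered 171 with no filter, 46 with DESeq2, 13 with voom, 0 in 1 fit of all libraries, 20 with a replicate block, 2 with the striatal covariate, 0 without Tcf20+/- replicates 1 and 2, and 0 to 58 leaving out 1. Genes changed in Phf14+/- against WT numbered 261 with no filter, 69 with DESeq2, 6 with voom, 1 with the olfactory covariate, 5 at equal depth, 5 at an adjusted p under 0.1, and 1 to 7 leaving out 1. Removing Tcf20+/- replicates 1 and 2 leaves 1 library, which is assumed to vary like the WT libraries. The targeted gene Phf14 in Phf14+/- was at -0.0373 with the olfactory covariate and -0.0607 to 0.106 leaving out 1.

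The genes whose change differs between MeCP2 KO and Tcf20+/- numbered 730 with DESeq2, 244 with a replicate block, 42 without Tcf20+/- replicates 1 and 2, and 205 to 836 leaving out 1. The genes whose change differs between MeCP2 KO and Phf14+/- numbered 838 with DESeq2, 251 with a block and 257 to 695 leaving out 1. The genes whose change differs between Tcf20+/- and Phf14+/- numbered 9 with DESeq2, 4 with no filter and 2 to 6 leaving out 1. The correlation of log2 fold changes, Tcf20+/- and Phf14+/-, turned to 0.0326 for genes at or above 10 CPM, 0.0385 as rho and 0.00726 with a replicate block, and ran from -0.0395 to 0.0581 leaving out 1. For MeCP2 KO and Tcf20+/- it ran from -0.0416 to 0.0972.

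In MeCP2 KO gene sets in Tcf20+/-: genes higher in MeCP2 KO had 0.0412 with an adjusted p of 0.703 with an estimated correlation, and 0.018 to 0.0727 leaving out 1, and genes lower in MeCP2 KO -0.0245 to 0.0743. MeCP2 KO gene sets in Phf14+/-: genes higher in MeCP2 KO turned to -0.0194 for the 200 smallest p and ran from -0.00627 to 0.0272, while MeCP2 KO gene sets in Phf14+/-: genes lower in MeCP2 KO had 0.0439 with an adjusted p of 0.465 with an estimated correlation, and 0.0303 to 0.0583. With an estimated correlation 0 lists were called in each line by camera (unadjusted p under 0.05 in 3, 1 and 1), where its preset called 11 in Tcf20+/-, 7 in Phf14+/- and 12 in MeCP2 KO. In Tcf20+/- 17 were called without replicates 1 and 2 and 10 to 18 leaving out 1. Called lists lost their call most often in Phf14+/-, microglial markers in 5 of 8 settings and autism and axon guidance genes in 4. In Tcf20+/- glutamatergic synapse genes and microglial markers lost it in 4 of 9, and in MeCP2 KO mitochondrially encoded genes in 4 of 13. The measure of gene length and fold change in MeCP2 KO gave 0.127 (exact p = 0.0556) at 50 kb, 0.151 (exact p = 0.0794) at or above 10 CPM, and 0.0992 to 0.186 leaving out 1.

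Of the 85 called genes named in MeCP2 KO, 1470 of 1615 values kept their call and direction, 145 lost the call and 0 turned. Of 19 settings the call was lost in 13 for Syt6, in 9 for Cntnap2, Foxp1, Hbb-bt, Nxph4 and Pdia3, and in 8 for Gabra2, Gng7, Grik5 and Rarb. In Phf14+/- Fn1 lost its call in 7 settings of 14 and Gm43305 in 0, and in Tcf20+/- Bhlhe40 lost its call in 6 of 15. In Tcf20+/- 16 values of genes without a call turned. With the striatal covariate they were Aspa -0.0859, C4b -0.0269, Ctss -0.027, Dlx2 -0.301, Gfap -0.0398, Hapln2 -0.371, Hs3st4 -0.0222, Notch3 -0.0151, Ogn 0.0473, Snap25 2.74e-04, Sp8 -0.1001, Sv2c -0.0859 and Tmem119 -0.0325. Without Tcf20+/- replicates 1 and 2 they were Ctss in Tcf20+/- at -0.000149, Dlx2 -0.208 and Hapln2 -0.205. The cause was not tested, except that fewer libraries leave less to call with. At these depths edgeR recovered 72 to 86% of genes changed 1.5-fold in simulated counts, so smaller changes are often missed. A sex covariate was not run, since the libraries show 1 sex.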

Other observations

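Genes near the targeted loci and gene families were also examined, by tests chosen after the main results were seen. Within 10 Mb of Mecp2, 17 of 96 genes had an unadjusted p under 0.05 in MeCP2 KO, 17.7% against 25.7% of other genes, and 6 were called, Irak1 among them (Fisher's exact test, adjusted p = 0.237). Within 10 Mb of Tcf20 it was 17 of 320 genes in Tcf20+/- (5.31% against 5.81%, adjusted p = 0.809), and around Phf14 4 of 65 in Phf14+/- (6.15% against 9.19%, adjusted p = 0.78). In each line the share near the targeted gene lay below that of other genes, by less than the tests could tell apart.

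Gene families were grouped by the stem of their symbol in MeCP2 KO, for stems with at least 10 tested members, which gave 202 families. By Fisher's exact test 0 families passed an adjusted p of 0.05, and 16 had an unadjusted p under 0.05. The family nearest to it was Prss, of serine proteases, with 5 falls among 16 members (adjusted p = 0.224), followed by Rassf, of Ras association domain proteins, with 4 rises among 10 (adjusted p = 0.277).

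Wdfy1, an endosomal protein gene, stood out among Phf14+/- libraries, at 31.5, 15.1 and 14.3 CPM in replicates 1 to 3 against 28 to 31.4 in WT. It lay between 45.4 and 55.9 CPM in the MeCP2 line. Gm43305, lower in Phf14+/-, was at 0 to 0.00957 CPM in all 10 libraries of the MeCP2 line, whose strain differs, and between 4.84 and 9.68 CPM in the Tcf20+/- line.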
